A study of Maylandia zebra with 2 samples.

How the data were processed

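Single-nucleus RNA sequencing was made from oral lamina of the upper and the lower jaw of *Maylandia zebra*, 2 samples with 1 library each. Per the labels' protocols, nuclei were freed by lysis, stained with DAPI, sorted as DAPI-positive singlets, and prepared with the 10x Chromium V3 gene expression kit for a target of 3000 nuclei per sample, at 413 and 403 nuclei per microlitre for the upper and lower jaw, and sequenced on a NextSeq 500. A further collection that the protocol names, from regenerating teeth, was not used here.

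The deposited matrix holds raw UMI counts per gene and barcode, made with Cell Ranger 3.1.0 per the file headers and the labels' processing tools. It covers 28622 features, each an Ensembl identifier paired with a name, of which 15894 names are gene symbols and 1142 carry the words 1 of many. The genome build and the alignment settings are not given in the sources used here, so no coordinates are printed. Of the symbols, 11608 also occur in the RefSeq gene table, which holds 0 Ensembl identifiers and was used for nothing else. The deposited metadata give per barcode the authors' cluster number, cell type name, a mark for kept nuclei and a score named cyto, and the sources give no rule for any of them. Tested on all 1381 barcodes, the kept mark equals a filter of more than 300 and fewer than 2500 genes, which removed 44 barcodes below and 41 above. The deposited score has 1296 distinct values in steps of 1 divided by 1295, and is read as a rank only. The column for the sample holds 1 distinct value and both jaws share the matrix, so nuclei could not be assigned to a jaw.

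All results were computed from the raw counts of the 1296 kept nuclei. UMIs were summed per class or cluster and scaled to CPM, and each sum was set against the sum of all other kept nuclei. Ratios carry exact conditional 95% intervals and CPM values exact Poisson intervals. Shares of nuclei carry Clopper-Pearson intervals. Since the jaws form 1 pooled sample, no p is given, no genes were counted as differing, and intervals cover counting error only. Depth per class sets the precision, with a floor of 3 UMIs equal to 2.11 CPM over all kept nuclei and to 113 CPM in Immature TB. Where a gene had 0 UMIs in a group, the ratio was bounded with that floor over the group.

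Gene lists (18 of cell type markers and 10 of pathways) and the rule for naming genes were fixed before the data were examined, as were the comparisons and the alternatives unless stated otherwise. A member matches a feature by its symbol, with or without a paralogue suffix a or b, and counts as measured from 10 UMIs in the kept nuclei. A member shared by several lists, such as *sox2*, *prox1a* or *krt18b*, counts in each. For each list the median log2 fold was taken with a prior count of 0.5 UMI per sum, with an interval from 2000 Poisson resamples and a percentile among 10000 random lists of the same size matched on expression in 20 bins. Members were counted as higher or lower from 2-fold, and members whose 0 count cannot resolve 2-fold as unresolved. List medians by suffix use the prior count only, so members with 0 UMIs in a small set can make them negative whatever their level. Near-identical gene copies can share reads, so features named 1 of many are uncertain.

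Named genes were, per class, the 5 with the largest fold among symbols with at least 20 UMIs in the class and a UMI in at least 25% of its nuclei. For the pair of taste bud classes they were the 8 highest and 8 lowest ratios among symbols with at least 30 UMIs in the pair and a UMI in at least 25% of the nuclei of the higher class. Per list they were up to 4 members with the highest fold in any class, among members with at least 20 UMIs, and all members of the odontogenic and dental stem lists with at least 50 UMIs. Not every gene that these rules name is printed. Other genes named were chosen after their values were seen. These are *alas2*, *bmp2b*, *fgf8a* and *fgf8b*, members of the cartilage and pigment lists named for their few UMIs, and the genes named by cluster.

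Detection was compared after thinning nuclei to 500 UMIs, the 20th percentile rounded down to a multiple of 50, and, as an alternative, to 800 UMIs. Shallower nuclei were left out, at 500 UMIs 114 Epithelial, 43 Immune, 17 Pigmented, 8 Mesenchymal and 0 taste bud nuclei. Other alternatives were a mean over nuclei, TMM factors from edgeR 4.0.16 in R 4.3.3, other UMI minimums, a prior count of 2, nuclei without the lowest 20% or the highest 5% of UMIs, the total without the 93 ribosomal protein features (1.67% of UMIs; 0 features are named as mitochondrial), and nuclei without Scrublet calls at an expected rate of 0.06. Own Leiden clusters (resolution 1.0, 2000 variable genes, 30 components, 15 neighbours) gave 16 clusters, in which 93.0% of nuclei fell in their deposited class, and 14 clusters with 93.6% when list genes were left out. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9 were used.

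The ratio step was tested on simulated data for the Mesenchymal class against other nuclei over 9333 genes. The sums were drawn as Poisson counts, the model that the intervals assume. Variation between nuclei was left out, so coverage under it was not tested. For genes simulated at 4-fold, 90.0% of intervals held the true fold and the median fitted log2 fold was 1.96. At 2-fold these were 100.0% and 0.95, for genes without a difference 97.3% and −0.04, at 0.5-fold 98.0% and −0.94, and at 0.25-fold 100.0% and −2.36. For the list step, 4.00% of 200 random lists of 15 genes over 12230 genes lay above percentile 95 and 4.50% below percentile 5. The comparison of the jaws and the edgeR test of classes within jaws were planned and not made, since no file maps nuclei to jaws. Coordinates of the deposited embedding were left out.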

Results

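The study sampled the oral lamina, the sheet of soft tissue that lies beside the replacement teeth, in the cichlid fish *Maylandia zebra* from Lake Malawi. This fish replaces its teeth throughout life, and the study's title concerns dental cell types shared among vertebrates. The question put to the counts was therefore which cell types the tissue holds and where genes of tooth, stem cell and taste bud biology are read. RNA was counted in single sorted nuclei from the upper jaw, from which 20668 nuclei were collected, and from the lower jaw, from which 20181 were collected, with 1 library per jaw. The deposited matrix held 1381 barcodes, 809 ending in suffix 1 and 572 in suffix 2, and no file maps a suffix to a jaw. All nuclei were described as 1 pooled sample without replicates, no comparison of the jaws was made, and values of the suffix sets stand side by side without a test.

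The authors kept 1296 nuclei, which held 1423040 UMIs (unique molecular identifiers, 1 per counted RNA molecule). The median kept nucleus had 832.5 UMIs, with a range of 367 to 5326, and 590.0 genes. Suffix 1 held 754 kept nuclei with a median of 753 UMIs, and suffix 2 held 542 with a median of 919. A count of 3 UMIs, the floor used where a gene had none, equals 3.27 CPM (UMIs scaled to a common total) in the Epithelial class, 27.2 CPM in the Mesenchymal class and 119 CPM in the Mature TB class. Folds are ratios of CPM between a class and all other kept nuclei, and the 95% intervals in parentheses cover counting error only.

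A tooth-bearing lamina is a layered epithelium over connective tissue, with blood-borne cells, pigment cells and taste buds among them. The share of each kind among the nuclei describes this preparation, since sorting and lysis can favour some nuclei over others. The authors named 6 classes over 12 clusters. Epithelial nuclei numbered 808 and made up 62.3% (59.6–65.0, Clopper-Pearson) of the kept nuclei. Immune nuclei numbered 266, a share of 20.5% (18.4–22.8). The Pigmented class held 98 nuclei (7.56%, 6.18–9.14) and the Mesenchymal class 85 (6.56%, 5.27–8.05). Taste bud nuclei were few, with 21 in the class named Mature TB (1.62%, 1.01–2.47) and 18 in the class named Immature TB (1.39%, 0.825–2.19). The Mesenchymal share was 7.56% (5.78–9.68) in suffix 1 and 5.17% (3.46–7.38) in suffix 2. Within the epithelium, cluster 0 made up 13.5% (11.2–16.2) of suffix 1 and 24.4% (20.8–28.2) of suffix 2, while cluster 3 made up 14.3% (11.9–17.0) and 9.23% (6.93–11.98). Cluster 0 was deeper, with a median of 1703 UMIs against 565 in cluster 3, and suffix 2 was the deeper set. Depth and composition were not told apart in these shares.

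**Figure D1:**
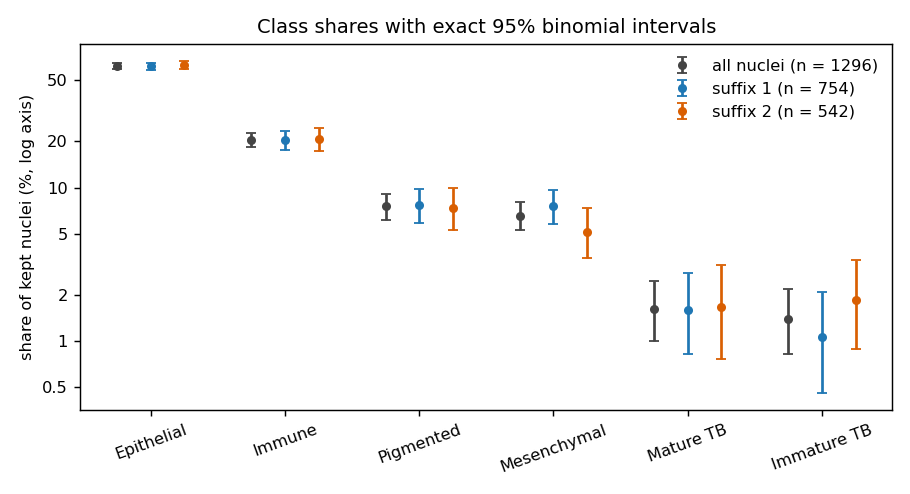
Share of kept nuclei (%, log axis) in each deposited class, for all nuclei and for each barcode suffix, as points with exact 95% binomial intervals. Epithelial nuclei lead at 62.3%, and the intervals of suffix 1 and suffix 2 overlap in every class.

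Epithelial nuclei are the tissue from which fish teeth and taste buds form. *krt5* codes for a keratin of the epithelial cytoskeleton, *epcam* for an adhesion protein of epithelial cells and *ppl* for periplakin, a protein of desmosomes and the cell envelope. *apoeb* codes for a lipid carrier, and *postnb* for a secreted matrix protein. These genes lead a class that was itself built from expression, so they describe its identity. The feature named *epcam* (1 of many), ENSMZEG00005018110, was 3.89-fold higher (3.30–4.62) in the Epithelial class than in other nuclei, and *ppl* was 3.69-fold higher (2.84–4.87). *krt5* was 3.34-fold higher (3.19–3.497) and *postnb* 3.31-fold higher (2.58–4.30). *apoeb* was 3.57-fold higher (3.14–4.08), but over all nuclei the Immature TB class held as much of it, with a log2 fold of −0.04 against that class. That level rests on 27.8% of the 18 Immature TB nuclei, and 48 of their 52 UMIs lay in suffix 1. The 5 genes were higher in both suffix sets, from 2.77-fold for *krt5* in suffix 1 to 5.14-fold for *ppl* in suffix 2.

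The fixed epithelium list had 15 of its 19 measured members at least 2-fold higher in the Epithelial class, with a median log2 fold of 1.37 (1.25–1.49) at percentile 100 of random lists matched on expression. Among its members, *evpla*, which codes for envoplakin, was 4.35-fold higher (3.24–5.94). The keratin gene *krt18b* went the other way and was 13.6-fold higher (10.5–17.7) in the Pigmented class, with 116 of its UMIs there. The epithelial transcription factor gene *grhl2b* was 6.60-fold higher (3.18–12.4) in the Immature TB class, and *itga6a* was 7.94-fold higher (2.82–21.1) in the Mesenchymal class. The desmosome and barrier list had a median of 1.45 (1.20–1.57) in the Epithelial class, with 11 of 13 members at least 2-fold higher. Its members *grhl1* and *evplb* were 3.20-fold (2.04–5.22) and 3.16-fold (1.98–5.30) higher. The hemidesmosome and basement membrane list had a median of 0.60 (0.50–0.92) at percentile 88.8. *DST*, which codes for dystonin, was 3.99-fold higher (2.90–5.38) in the Immature TB class, while *lama5* had only 2 UMIs in Mature TB nuclei, a ratio of 4.62 (0.529–18.6).

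The epithelial clusters differed in how they use these junction genes, which separate basal cells, held to the basement membrane by hemidesmosomes, from the cells above them, held to each other by desmosomes. This view by cluster, and the genes named in it, were chosen after their values were seen. *itga6b* and *itgb4* code for the integrin pair of hemidesmosomes. *itga6b* was 1.95-fold (1.82–2.09) higher in cluster 0, 2.02-fold (1.85–2.20) in cluster 1 and 2.40-fold (2.15–2.67) in cluster 7, and its fold was 0.230 (0.176–0.296) in cluster 3 and 0.221 (0.174–0.277) in cluster 4. *itgb4* followed the same split, from a fold of 2.52 (2.17–2.91) in cluster 7 to 0.243 (0.177–0.327) in cluster 4. The hemidesmosome list had medians of 0.58, 0.81 and 0.77 in clusters 0, 1 and 7, against −1.24 (−1.99 to −0.97) in cluster 3 and −1.95 (−2.18 to −1.67) in cluster 4. With absent members at the floor the last 3 were 1.30, −0.89 and −1.38. The desmosome and barrier list was highest in the clusters low in the hemidesmosome list, with medians of 1.97 (1.64–2.41) in cluster 4 and 0.86 (0.59–0.99) in cluster 3, against 0.02 (−0.33 to 0.10) in cluster 0, −1.19 in cluster 1 and −0.94 (−0.62 with absent members at the floor) in cluster 7. *evpla* was 16.7-fold higher (13.8–20.4) in cluster 4, where 291 of its 455 UMIs lay.

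**Figure D2:**
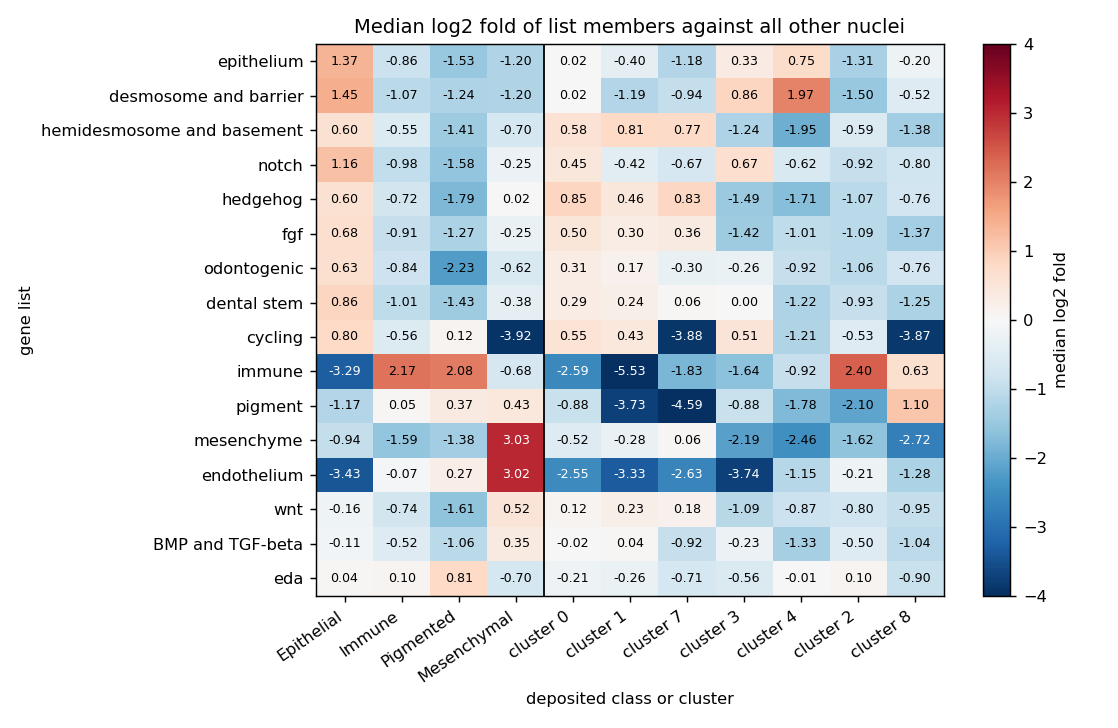
Median log2 fold (colour and printed value) of the members of 16 gene lists, one list per line, in 4 classes and 7 clusters against all other nuclei. The hemidesmosome list is above 0 in clusters 0, 1 and 7 and below 0 in clusters 3 and 4, and the immune list is high in the Immune (2.17) and Pigmented (2.08) classes.

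Notch, hedgehog and FGF signals pattern tooth germs in many vertebrates. *notch1a* and *notch3* code for receptors, *jag2b* for a ligand and *her9* for a repressor downstream of the pathway. *her9* was 5.41-fold higher (2.49–14.0) in the Epithelial class, *notch1a* 3.99-fold (2.12–8.32) and *jag2b* 2.603-fold (2.07–3.31), while *mfng* was 7.67-fold higher (5.44–10.9) in the Immune class. The notch list had a median of 1.16 (0.12–1.35) in the Epithelial class, but it differed by suffix, at −0.04 in suffix 1 and 1.48 in suffix 2. Among clusters, *notch3* was 4.76-fold higher (3.72–6.06) in cluster 3, a gene and cluster chosen after the values were seen. For hedgehog, *smo*, which codes for the signal transducer, was 8.78-fold higher (2.24–75.7) in the Epithelial class on 32 UMIs against 2 elsewhere. The ligand gene *shha* and the co-receptor gene *cdon* had 3 UMIs each in Immature TB, with ratios of 4.52 (0.890–14.4) and 4.40 (0.867–13.9). The hedgehog list had a median of 0.60 (0.31–0.93) in the Epithelial class, 0.85 (0.46–1.09) in cluster 0, −1.49 (−1.82 to −0.50) in cluster 3 and −1.71 (−2.29 to −0.88) in cluster 4.

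The FGF list had a median of 0.68 (0.29–1.00) in the Epithelial class and 1.10 (−0.46 to 1.63; 1.61 with absent members at the floor) in Immature TB, where it was −1.04 in suffix 2 alone. *fgf18a*, a ligand gene, was 3.29-fold higher (1.47–8.69) in the Epithelial class. *spred1*, which codes for an inhibitor of the pathway, was 4.798-fold higher (1.70–11.01) in Immature TB, and *dusp6*, a feedback phosphatase gene, was 5.40-fold higher (2.33–11.5) in the Pigmented class. The transcription factor gene *etv4* had 6 UMIs in Immature TB, a ratio of 3.07 (1.10–6.92). Ectodysplasin signalling shapes teeth and scales, and its receptor gene *edar* was 2.48-fold higher (1.57–4.09) in the Epithelial class, with the related *TNFRSF19* 2.58-fold higher (1.80–3.79). *relt* and *nfkbiab* were 7.29-fold (2.49–19.3) and 2.23-fold (1.51–3.21) higher in the Pigmented class. The ectodysplasin list as a whole stood at 0.04 (−0.47 to 0.66) in the Epithelial class and at 0.81 (−3.90 to 1.14) in the Pigmented class.

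Tooth formation begins in dental epithelium that expresses *dlx* genes, and stem cells of the dental epithelium in other vertebrates carry *sox2*, *lgr* and *lrig1*. Where these genes are read in the lamina beside the teeth was asked with lists fixed in advance. The odontogenic list had a median of 0.63 (0.26–0.88) in the Epithelial class at percentile 99.7, with 7 of 20 members at least 2-fold higher, and −2.23 (−0.98 with absent members at the floor) in the Pigmented class. *dlx4b* was 5.03-fold higher (2.77–10.0) in the Epithelial class and *dlx3b* 2.13-fold (1.57–2.94). *pitx1* was 1.97-fold higher (1.64–2.38), *wnt10a* 1.97-fold (1.42–2.77) and *wnt7bb* 1.58-fold (1.22–2.08). *ctnnb1* had a fold of 1.41 (0.952–2.12), an interval that includes 1. *sox2*, *lef1*, *runx2b* and *msx1a* were not higher there than in all other nuclei together, with folds from 0.627 for *msx1a* to 0.880 for *runx2b*. For *sox2* those other nuclei include the 70 UMIs of Immature TB, at 2646 CPM. By cluster *sox2* ran from 42.4 CPM (cluster 7) to 249 CPM (cluster 3) in the epithelium. In the remaining clusters outside Immature TB it stood at 119 CPM or less. *sox2* was 19.8-fold higher (14.8–26.1) and *lef1* 9.60-fold higher (5.26–16.5) in Immature TB, *msx1a* was 6.06-fold higher (3.74–9.64) in the Mesenchymal class, and *pax9* was 25.9-fold higher (8.93–67.4) in Mature TB on 7 UMIs. *bmp2b*, *fgf8a* and *fgf8b* had 0 of the 1423040 UMIs, which allows up to 2.11 CPM for each.

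The dental stem cell list had a median of 0.86 (0.37–0.96) in the Epithelial class at percentile 99.9, although 4 of its 14 members were at least 2-fold higher and 4 at least 2-fold lower. *LGR6*, which codes for a receptor that strengthens Wnt signals, was 3.65-fold higher (2.35–5.93) and the keratin gene *krt15* 3.05-fold higher (2.82–3.30). *yap1* was 2.15-fold higher (1.64–2.85), *lrig1* 1.90-fold (1.31–2.82), *celsr1a* 1.87-fold (1.44–2.45), *gli1* 1.85-fold (1.30–2.69) and *lgr4* 1.79-fold (1.34–2.41). *bmi1a* had a fold of 1.12 (0.658–1.96). *pknox2*, a homeobox gene, and *spock1*, a proteoglycan gene, went with the Mesenchymal class instead, at 86.4-fold (30.3–338) and 12.9-fold (5.43–30.9) higher. In Mature TB the list stood at −4.92, and at −0.04 with absent members at the floor.

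Fish oral tissue carries resident lymphocytes and phagocytes. *skap1* and *sh3kbp1* code for signalling adaptors, *jak3* for a cytokine receptor kinase and *BCL11B* for a transcription factor of T cells. In the Immune class *sh3kbp1* was 10.1-fold higher (7.15–14.4), *skap1* 9.50-fold (6.82–13.4), *PRKD3* (1 of many), ENSMZEG00005013100, 9.44-fold (7.24–12.4), *jak3* 8.72-fold (6.18–12.4) and *BCL11B* 8.33-fold (5.95–11.8). The immune list had a median of 2.17 (1.94–2.47) there, with 12 of 16 members at least 2-fold higher, and −3.29 (−3.51 to −2.86) in the Epithelial class. *coro1a*, an actin regulator gene of blood cells, was 12.3-fold higher (7.67–20.4). The clusters of the class were unlike each other, with list medians of 2.40 in cluster 2, 0.63 in cluster 8 and 0.44 (1.36 with absent members at the floor) in cluster 9. *prox1a*, a homeobox gene on both taste bud lists, was 10.4-fold higher (6.73–16.2) in the Immune class, and *foxa3*, a gene of the goblet cell list, was 15.6-fold higher (6.03–47.3). Cluster 8, with 50 of the 266 nuclei, carried both, with 69 of the 71 *prox1a* UMIs of the class and all 20 *foxa3* UMIs. Immature TB held *prox1a* too, with 8 UMIs at 302 CPM (131–596) in 38.9% of its nuclei. *pax5*, a B cell transcription factor gene, had 6 UMIs in Mature TB, a ratio of 11.1 (3.77–27.1).

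Pigment cells of fish are black, yellow or silvery, and *mitfa* codes for the transcription factor that black pigment cells need. *stab1* and *mrc1b* code for scavenger receptors, *ncf4* for a subunit of the phagocyte oxidase and *slc43a2a* for an amino acid transporter. *slc43a2a* was 50.7-fold higher (32.2–82.6) in the Pigmented class, with 32.7-fold in suffix 1 and 145-fold in suffix 2. *stab1* was 48.0-fold higher (36.7–63.3), *mitfa* 44.6-fold (25.4–82.2), *mrc1b* (1 of many), ENSMZEG00005020331, 43.2-fold (28.5–67.2) and *ncf4* 29.6-fold (18.7–48.0). The pigment list reached only 0.37 (−1.75 to 1.44, and 0.81 with absent members at the floor) at percentile 76.7. In suffix 1 alone it was −3.09 with the prior count only, a value that absent members can set. The immune list stood at 2.08 (1.81–2.20) with 12 of 16 members at least 2-fold higher. The macrophage receptor gene *csf1ra* was 37.2-fold higher (16.6–91.4) and the myeloid transcription factor gene *spi1b* 21.9-fold higher (11.6–42.1). *id2a* and *smad7*, genes of the BMP and TGF-beta list, were 9.87-fold (5.39–17.7) and 6.36-fold (3.76–10.4) higher. *mitfb*, the sister gene of *mitfa*, was 2.48-fold higher (1.29–4.60) in the Immune class.

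Mesenchymal cells make the connective tissue under the epithelium and, in teeth, the pulp and the dentine. *prrx1b* codes for a homeobox factor of mesenchyme, *glis1a* and *glis1b* for zinc finger factors, *ptx3b* for a pentraxin and *slc7a9* for an amino acid transporter. *glis1a* had 37 UMIs in the Mesenchymal class and 1 elsewhere, a ratio of 441 (74.4–17877). *ptx3b* was 414-fold higher (158–1541), *glis1b* 250.2-fold (94.2–939.6), *slc7a9* 188-fold (77.4–596) and *prrx1b* 140.0-fold (51.2–535). The mesenchyme list had a median of 3.03 (2.70–3.41), with 17 of 20 members at least 2-fold higher, among them *col6a2* at 95.3-fold (37.6–309), *COL6A3* at 50.6-fold (35.7–73.4) and the fibrillin gene *FBN1* at 41.7-fold (16.3–126). The Wnt list stood at 0.52 (0.13–0.99) in this class, at percentile 99.98 of random lists. *sfrp2*, which codes for a secreted Wnt antagonist, had 60 UMIs here and 1 elsewhere, a ratio of 715 (123–28701). *sfrp1a* was 8.66-fold higher (5.85–12.8) and the Wnt receptor gene *ror2* 22.6-fold higher (10.0–54.5). The BMP and TGF-beta list was at 0.35 (−0.15 to 0.79), with *smad1* 3.28-fold higher (1.52–6.51) and *fsta* at 2 UMIs in Immature TB, a ratio of 5.56 (0.627–23.0).

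The Mesenchymal class also held transcripts of genes on lists for other tissues. The cartilage list had 3 measured members and a median of 6.03 (4.51–6.96; 6.57 with absent members at the floor), 5.92 in suffix 1 and 4.13 in suffix 2, with the cartilage link protein gene *hapln1a* 95.3-fold higher (28.9–494) on 24 UMIs against 3. Its member *sox9b* was 2.81-fold higher (1.68–4.94) in the Epithelial class. *col2a1a*, *matn1*, *comp* and *col11a2*, also on this list, had 0 UMIs in all kept nuclei, and *acanb* had 1. The median thus rests on few genes and does not show cartilage cells. The endothelium list stood at 3.02 (1.84–3.47) in Mesenchymal nuclei. In suffix 2 alone it was −0.06 with the prior count only, a value that absent members can set. The endothelial factor gene *fli1a* was 18.5-fold higher (7.47–48.5) and the receptor gene *flt4* 6.38-fold higher (3.17–12.4), while *fli1b* was 7.56-fold higher (5.71–10.0) in the Immune class. *pnp4a* and *ltk*, genes of silvery pigment cells, were 53.6-fold (17.7–218) and 7.94-fold (3.19–18.9) higher in the Mesenchymal class, where the pigment list stood at 0.43 (−0.26 to 1.80; 1.25 with absent members at the floor). The 18 UMIs of *pnp4a* in this class came from 2.35% of its 85 nuclei.

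Lists for further cell types were less decisive. The mural list stood at 0.37 (−0.19 to 1.25) in the Mesenchymal class, with the pericyte receptor gene *pdgfrb* 10.998-fold higher (4.59–26.1) and *tagln* 1.87-fold (1.47–2.37). The glia list stood at 0.59 (−0.37 to 1.06) there, with *pmp22a* 3.90-fold higher (2.11–6.85), while *ngfrb* was 2.26-fold higher (1.54–3.42) in the Epithelial class and *mbpb* had a fold of 1.38 (0.625–2.65) in Mature TB. The neuron list stood at 0.05 (−1.004 to 1.27; 1.16 with absent members at the floor) in the Mesenchymal class, where *rbfox3a* was 2.49-fold higher (1.29–4.47). *rbfox3b* had a fold of 1.46 (1.06–2.00) in the Immune class. The mineralising list stood at −0.19 (−0.42 to 0.89) in the Epithelial class with 0 of 5 members past 2-fold, where *sparc* and *alpl* had folds of 1.94 (1.57–2.40) and 1.65 (1.10–2.52). The osteoclast list stood at 1.09 (−1.07 to 2.03) in the Mesenchymal class and at 1.06 (−1.96 to 1.71; 1.29 with absent members at the floor) in the Pigmented class, with the collagen protease gene *ctsk* 2.77-fold higher (1.39–5.12), and the ionocyte list at 0.60 (−0.14 to 1.04) in the Immune class. *slc12a2*, an ion transporter gene, was 3.87-fold higher (2.39–6.09) in the Mesenchymal class, and *atp1b1a* had a fold of 1.64 (0.682–3.41) in the Pigmented class. The cycling list stood at 0.80 (0.10–1.37) in the Epithelial class, 1.45 in suffix 1 and 0.12 in suffix 2, with *mcm5* 4.21-fold higher (1.27–21.9) and *hmgb2a* 2.23-fold higher (1.54–3.28). *pcna* had 4 UMIs in Immature TB, a ratio of 3.105 (0.822–8.32), and *cenpf* had a ratio of 2.83 (1.06–6.46) in the Pigmented class. The muscle, goblet and erythrocyte lists had too few measured members for a median. *dmd*, the dystrophin gene, was 4.25-fold higher (2.19–7.83) in the Mesenchymal class, and *alas2*, a haem synthesis gene, had 15 UMIs in all and a ratio of 3.64 (0.658–13.5) in the Pigmented class.

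Taste buds form from the same oral epithelium as teeth, and their receptor cells signal taste through PLCB2 and the channel TRPM5. *calb2a* codes for the calcium-binding protein calretinin, *avil* for the actin-binding protein advillin and *rap1gap* for a regulator of the GTPase Rap1. In the Mature TB class *calb2a* was 1483-fold higher (563–5543), with 107 UMIs against 4, and *PLCB2* 518-fold (160–2660) on 28 UMIs against 3. *rap1gap* had 25 UMIs against 2, a ratio of 693 (173–6038), and *avil* 20 against 3, a ratio of 370 (110–1943). *trpm5* was 360-fold higher (125–1421). The mature taste list stood at 2.39 (1.79–2.87; 2.73 with absent members at the floor) with 4 of 7 members at least 2-fold higher, but it was 0.77 over members with at least 50 UMIs and −1.01 over members with at least 1 UMI. TMM scaling shifted all folds of the Mature TB class by −0.51 log2 and those of the Immature TB class by −0.45, so a fold as small as that of *mbpb* in Mature TB has no fixed sign.

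In Immature TB nuclei the leading genes included *spire2*, which codes for an actin nucleator, *cacna1bb*, for a calcium channel, and *dpp6b*, for a partner of potassium channels. *spire2* was 330-fold higher (114–1304), *samd10b* 101-fold (46.4–231), *dpp6b* 60.3-fold (32.2–114), *cacna1bb* 52.8-fold (36.4–76.5) and *igsf9a* 45.9-fold (23.9–87.4). The lead of *igsf9a* over the next class was only 0.25 log2. The immature taste list stood at 0.72 (−0.66 to 1.33), at 1.58 in suffix 1 and −0.92 in suffix 2, so the pooled value has no fixed sign at this depth.

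The pair of taste bud classes was compared for the genes that part them, on 25210 UMIs in Mature TB and 26459 in Immature TB. Maturity is taken from the class names and was not tested. *myo3a* codes for a myosin of sensory cells, *ADGRL3* and *tenm1* for adhesion proteins of synapses, *unc5a* for a netrin receptor and *slc6a6b* for a taurine transporter. *sox2* codes for a transcription factor of taste bud progenitors, *fgfrl1a* for a receptor that binds FGF and *kcnq5b* for a potassium channel. In Mature TB *calb2a* was at least 37.4-fold higher, *tenm1* at least 23.8-fold, *slc6a6b* at least 17.8-fold and *unc5a* at least 14.0-fold, each with 0 UMIs in Immature TB, read as the floor of 3. *myo3a* had 102 UMIs against 1, a ratio of 107 (18.8–4269), and *ADGRL3* 80 against 1, a ratio of 84.0 (14.6–3357). *PTPRD* was 15.4-fold higher (6.80–43.1), and *gipc2* had 28 UMIs against 2, a ratio of 14.7 (3.71–127). In Immature TB *sox2* was at least 22.2-fold higher, *fgfrl1a* at least 20.96-fold and *cacna1bb* at least 19.4-fold, each with 0 UMIs in Mature TB. *xylt1* had 54 UMIs against 1, a ratio of 51.4 (8.85–2069.5), *kcnq5b* was 15.9-fold higher (7.04–44.3), *MYO1D* had 49 against 3, a ratio of 15.6 (5.02–78.1), and *iffo2b* was 7.15-fold higher (2.52–27.9). *apoeb* had 52 against 2, a ratio of 24.8 (6.52–210.0), but 48 of the 52 lay in suffix 1, and thinning all nuclei to one depth brought its log2 fold from −4.63 to −0.22. Thinning also brought *MYO1D* from −3.96 to −2.22. Both thinned values measure the effect of depth poorly, since Mature TB held only 2 UMIs of *apoeb* and 3 of *MYO1D* before thinning. *MYO1D* had a UMI in 77.8% of Immature TB nuclei and in 4.76% of Mature TB nuclei.

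**Figure D3:**
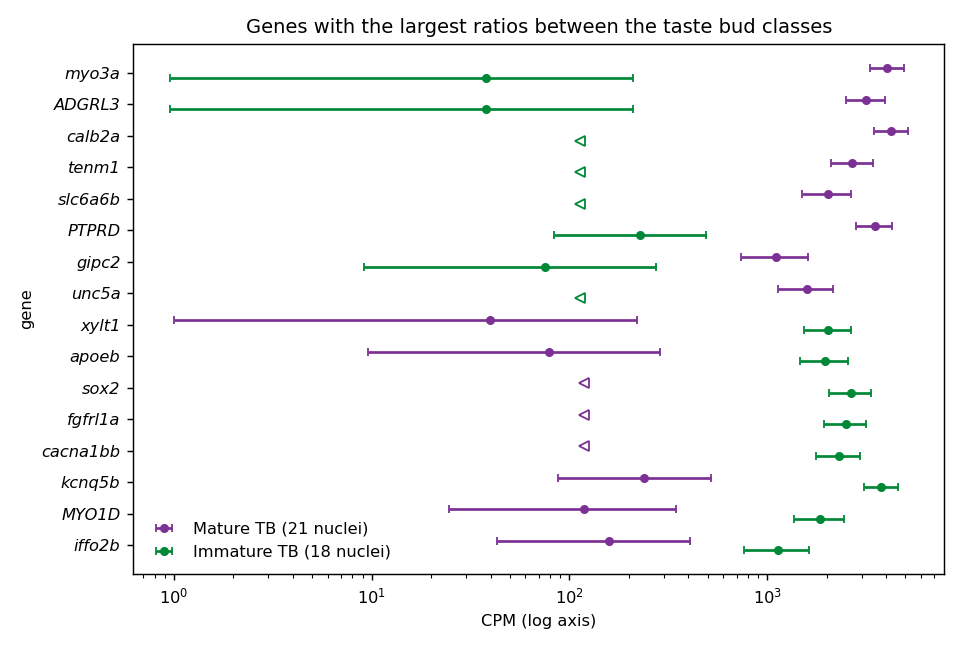
CPM (log axis) of the 16 genes with the largest ratios between Mature TB (21 nuclei) and Immature TB (18 nuclei), as points with exact 95% Poisson intervals, and open triangles at the floor of 3 UMIs where the count was 0. *calb2a* (107 UMIs) was not counted in Immature TB and *sox2* (70 UMIs) not in Mature TB.

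Free RNA in droplets can put a transcript in nuclei that do not make it, so shares of nuclei with a UMI were set beside those of the other nuclei at one depth of 500 UMIs. The origin of UMIs in those other nuclei was not tested. *krt5* was counted in 97.2% of Epithelial nuclei (median 840.5 UMIs) and in 79.3% of other nuclei (median 819 UMIs), and at one depth in 94.5% and 64.3%. *epcam* (1 of many) was counted at one depth in 39.5% of Epithelial and 13.8% of other nuclei. Shares in the other nuclei were far lower for genes of the smaller classes. *calb2a* was counted in 81.0% of Mature TB nuclei (median 1138 UMIs) and 0.314% of other nuclei (median 825 UMIs), and at one depth in 71.4% and 0.0915%. *stab1* was counted at one depth in 56.8% of Pigmented nuclei and 2.71% of others, *sh3kbp1* in 19.7% of Immune nuclei and 2.02% of others, and *spire2* in 38.9% of Immature TB nuclei and 0.0912% of others. *glis1a* was counted in 25.9% of Mesenchymal nuclei (median 986 UMIs) and in 0.0826% of others (median 819 UMIs), and at one depth in 12.99% and in 0 of 1037 nuclei, which allows a share of nuclei with a UMI at that depth of up to 0.289%, the floor of 3 nuclei.

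**Figure D4:**
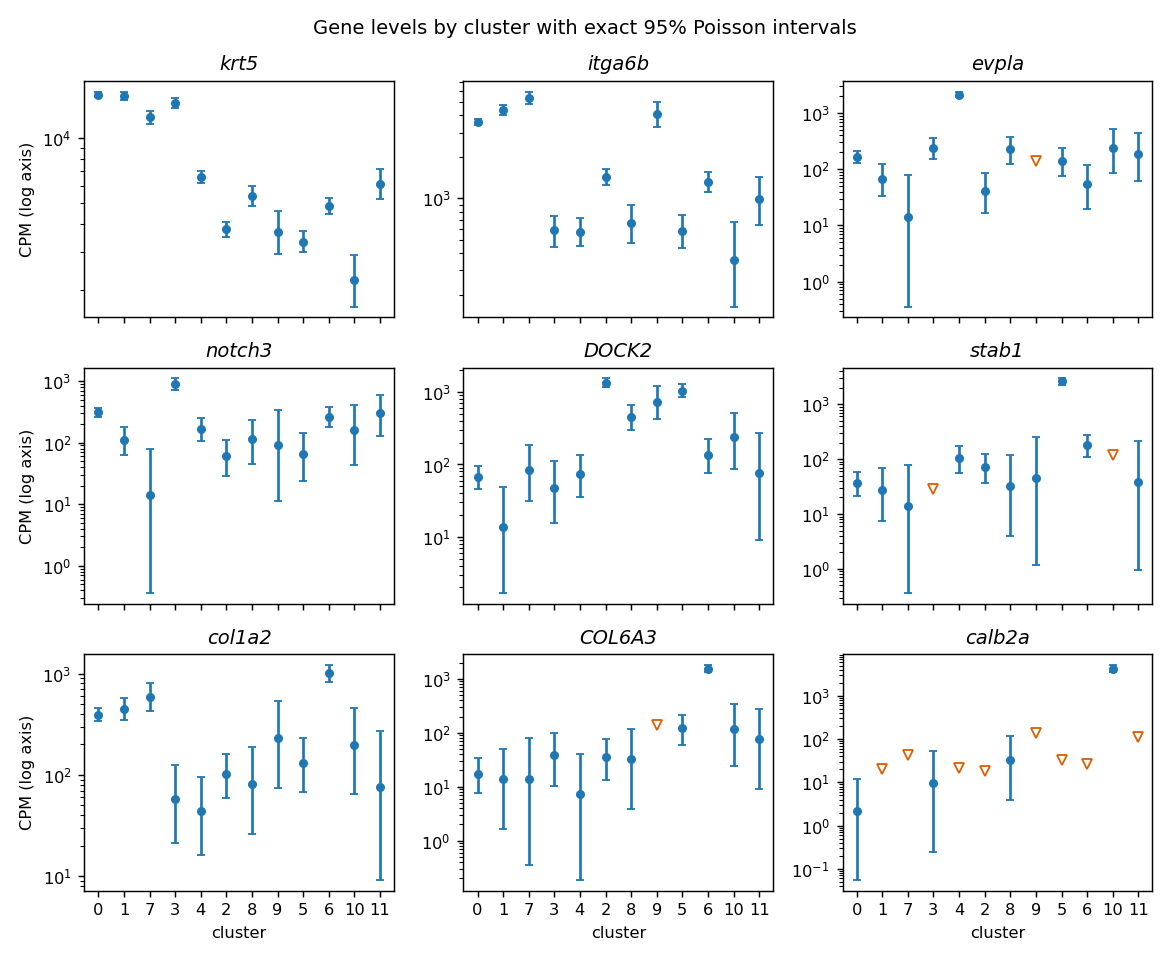
CPM (log axis) of 9 genes in the 12 deposited clusters, as points with exact 95% Poisson intervals, and open triangles at the floor of 3 UMIs where the count was 0. *krt5* stays above 2221 CPM in every cluster, whereas *evpla* peaks in cluster 4 at 2135 CPM and *notch3* in cluster 3 at 899.7 CPM.

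The deposited table also ranks the kept nuclei by a score named cyto, from 0 to 1 in equal steps, whose method is not given in the sources used here. Its highest medians were in epithelial clusters 0 (0.877, quartiles 0.749–0.943) and 7 (0.819, 0.765–0.896), followed by cluster 1 at 0.638 (0.535–0.761). The Pigmented class had the lowest, 0.107 (0.0533–0.223), with Mature TB at 0.217 and Immature TB at 0.345. Over the kept nuclei of this pooled sample the score went with the number of genes counted, with a Spearman rho of 0.442 and a Pearson r of 0.452, and within the Epithelial class rho was 0.606. Nuclei are not independent replicates, so no p is given.

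**Figure D5:**
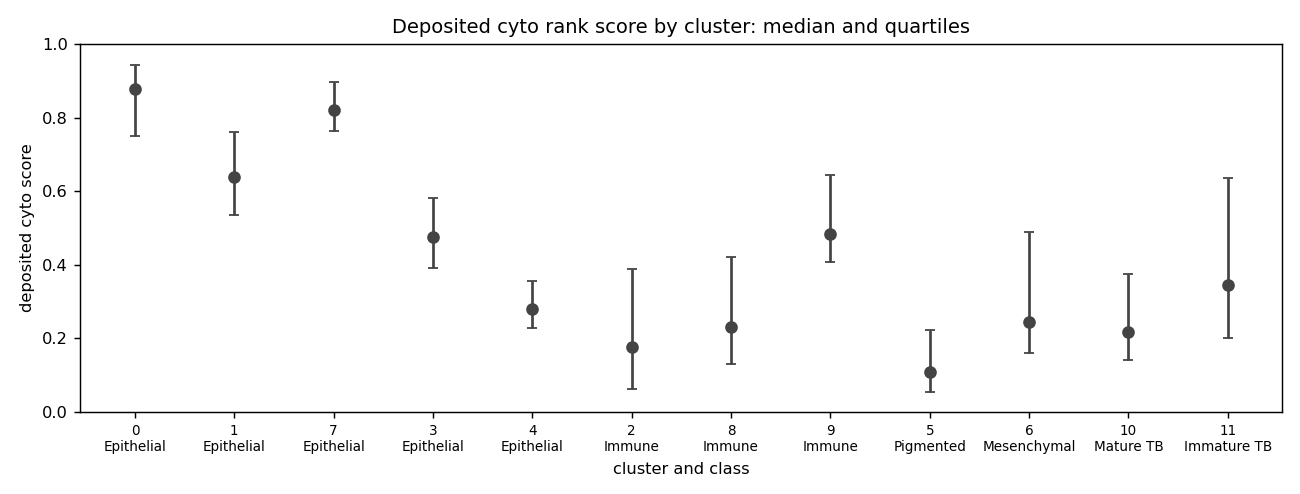
Deposited cyto score (0 to 1, a rank) in each cluster, as the median with quartiles, clusters ordered by class. Clusters 0 and 7 sit highest at 0.877 and 0.819, and cluster 5 (Pigmented) lowest at 0.107.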

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

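All tests in this part were chosen after the results were seen. A signal lay in barcodes that no comparison used, those outside the deposited filter. The 41 barcodes above it held 658114 UMIs, 31.4% of the 2098976 UMIs of all barcodes, and the 44 below it held 17822. The deepest barcodes held 134092 and 115495 UMIs. Above the filter *krt5* stood at 13244 CPM, *itga6b* at 2686 CPM, *runx3* at 407 CPM and *COL6A3* at 86.6 CPM, so genes of epithelial, immune and mesenchymal nuclei were all read there. Without the 2 deepest barcodes *runx3* stood at 294 CPM and *COL6A3* at 56.3 CPM. These levels do not show which kinds of nuclei the barcodes held. Below it *krt5* stood at 10885 CPM and *runx3* at 1122 CPM. No explanation of these barcodes was tested.

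Collagens I, V and XII form fibrils of connective tissue, yet their 7 genes were read in the epithelial clusters 0, 1 and 7 at 1999 CPM, against 349 CPM in clusters 3 and 4, 680 CPM in clusters 2, 5 and 8, 2256 CPM (1669–2982) in immune cluster 9 and 5699 CPM in the Mesenchymal cluster. If free RNA from mesenchymal nuclei reached all clusters alike, these levels would be similar. The level in clusters 0, 1 and 7 was instead 5.73 times (4.60–7.23) that in clusters 3 and 4. It was 2.72 times (2.39–3.095) that in all clusters neither epithelial nor mesenchymal. The even spread was assumed and not tested. The basal gene *itga6b* was uneven outside the basal clusters, at 1432 CPM in cluster 2 and 584 and 572 CPM in clusters 3 and 4. Cluster 9 also read the basal genes *itga6b* at 4097 CPM (3290–5042) and *itgb4* at 1795 CPM (1277–2454), near their levels in cluster 0 (3573 and 1833 CPM). The immune gene *DOCK2* stood at 737 CPM (421–1196) there, against 67.3 CPM in cluster 0. Why cluster 9 read both kinds of genes was not tested, and its collagen level was not explained. Doublets with mesenchymal nuclei would also bring collagen VI, but its 3 genes were at 0.0171 (0.0110–0.0257) of their mesenchymal level where the collagens were at 0.351, a ratio of 20.5 (12.4–35.2), and all 13 other members of the mesenchyme list together were at 0.117 (0.107–0.128). The collagen VI ratio argues against doublets as the whole origin of the signal. The comparison of clusters argues only against evenly spread free RNA, and leaves unevenly spread free RNA open. The design gives no biological explanation to test, so transcription of these collagens by the nuclei of clusters 0, 1 and 7 themselves may be held only as a hypothesis.

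In the Pigmented class the pigment list had a median log2 fold of only 0.37 (−1.75 to 1.44), although its member *mitfa* was 44.6-fold higher. Immune list transcripts stood at a median of 2.08 (1.81–2.20) there. If free RNA or doublets from the lymphocyte-rich cluster 2 brought them, the myeloid genes *mpx*, *cybb*, *spi1b* and *csf1ra* would be no higher than in that cluster, but their summed level of 941 CPM was 5.84 times (3.75–9.36) the 161 CPM there, while the lymphoid genes *lck*, *coro1a* and *pax5* stood at 0.195 (0.0977–0.354) of it. This argues against cluster 2 as the source of the myeloid genes, and leaves open the origin of genes both clusters read, such as *DOCK2* and *runx3*. A class made of myeloid nuclei with few pigment cells could be a candidate explanation, and predicts pigment members other than *mitfa* near the level of other nuclei. Their ratio was 1.45 (0.750–2.56), an interval too wide to decide on 13 UMIs. *pmelb*, *TYRP1*, *tyrp1b*, *slc24a5* and *gch2* had 0 UMIs in all kept nuclei, and *pmela*, *slc45a2* and *sox10* had 1 each. *mlphb* had 9, the most among members of the pigment list left out for few UMIs. Transcripts of these members were scarce in every class, which leaves the question undecided at this depth. No biological explanation was given by the design.

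Cluster 8 joined transcripts of the goblet list, *prox1a* and immune genes, which belong to secretory, sensory or lymphatic, and blood cells. If several kinds of nuclei share the cluster, clustering without list genes should part them, with the goblet list at least 2-fold higher in the second largest part. That clustering did divide it, into parts of 18, 14 and 10 nuclei. Of the nuclei outside these parts, 4 grouped mainly with cluster 3 nuclei and 4 mainly with cluster 2 nuclei. They count in the rest of the cluster. The goblet list ratio of the second largest part, of 14 nuclei, to the rest was 2.83 (1.23–6.50). This does not reach 2-fold by its lower bound, so the test did not decide. In the parts of 18, 14 and 10 nuclei the goblet list stood at 84.5 CPM (10.2–305), 852 CPM (454–1458) and 0 CPM (0–303). These parts held 2, 13 and 0 of the 27 goblet list UMIs of cluster 8, so many lay in the nuclei outside them. *prox1a* was 12.3 times (5.86–29.7) higher in the largest part, of 18 nuclei, but that ratio was picked once its values were known and is no test. In the same order of parts *prox1a* stood at 2578 CPM (1972–3311), 0 CPM (0–242) and 576 CPM (231–1186). Goblet list and *prox1a* transcripts were thus read mostly in different nuclei of the cluster. Doublets with lymphocytes cannot be told apart from several kinds of nuclei by the immune list, which in the second largest part stood at 0.340 (0.234–0.478) of cluster 2, an interval on both sides of the bound set for the test. Scrublet called 0 of the 50 nuclei, but it called only 1 of all 1296, and their median doublet score of 0.100 was the highest of the 12 clusters, against 0.0682 over all nuclei; no biological explanation was tested.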

How the results depend on the processing

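The tests by barcode suffix, with extra gene copies, by cluster number, without thinning and without the 6% of nuclei with the highest Scrublet scores were chosen after the data were seen. Of 442 alternative log2 folds for 46 gene results, 382 stayed within the counting interval, 59 moved beyond it with the same sign and 1 reversed. That was *apoeb* in the Epithelial class, at −0.044 against the next class. List medians were redone 365 times for 39 results. Among those that concern pathway lists and further cell types, 245 stayed within the interval, 26 moved and 2 reversed, where reversed means a change of sign of a value whose pooled interval excluded 0. These were notch in the Epithelial class at −0.041 in suffix 1 and endothelium in the Mesenchymal class at −0.061 in suffix 2. For the lists that define the classes, and for the odontogenic and dental stem lists, 76 stayed, 15 moved and 1 reversed. The reversed one was mature taste in Mature TB at −1.01 over members with at least 1 UMI, against 0.77 from 50 UMIs, 1.42 in suffix 1 and 3.03 in suffix 2. A mean over nuclei gave 1.55 for epithelium and 0.98 for dental stem in the Epithelial class and 1.72 for immune in the Pigmented class. Without the highest Scrublet scores epithelium stood at 1.52 and immune in the Immune class at 2.61. Own clusters without list genes gave 1.38 for immune in the Pigmented class. Mesenchyme in the Mesenchymal class was 2.70 from 50 UMIs and 2.65 in suffix 2, and dental stem was 1.06 in suffix 2. Pigment in the Pigmented class was −3.09 in suffix 1, and immature taste in Immature TB was 1.58 in suffix 1 and −0.92 in suffix 2. These also changed sign, as did FGF in Immature TB at −1.04 in suffix 2 and hedgehog in cluster 1 at −0.45 over members with at least 1 UMI, but they count as moved because their pooled intervals spanned 0. The values by suffix use the prior count only, so members with 0 UMIs in a small set may have set their sign. Of 42 alternative class shares 39 stayed within the interval. Own clusters gave 23.8% Immune and 5.94% Pigmented nuclei, and suffix 2 gave 5.17% Mesenchymal. Of 12 alternative detection shares 7 stayed and 5 moved. For all of these the cause was not tested. Leaving out Scrublet calls tests little, since 1 nucleus was called. The jaw comparison and its alternatives, the edgeR and DESeq2 tests of classes within jaws, and the mitochondrial part of one alternative were not run. No paired analysis was made, since no test was run. A fit of classes with barcode suffix as a block was not run. It would need only that the suffixes part the libraries, which no file states, and not which jaw each one is. Depth limits most the taste bud classes, where a gene with 0 UMIs can still be at 119 CPM in Mature TB.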

Other observations

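All values in this part were chosen after they were seen, and no tests were run on them. Several genes stood out in epithelial cluster 4. *cldnb* codes for a tight junction protein, *nox1* for an oxidase, *glulc* for glutamine synthetase, *mpx* for a peroxidase known from neutrophils and *cd74a* for the chain that guides antigen presentation. In cluster 4 the feature *lpcat4* (1 of many), ENSMZEG00005021145, was 39.9-fold higher (21.5–79.7) than in other nuclei, *glulc* 33.9-fold and *cldnb* 23.7-fold. *nox1* stood at 719 CPM (584–876) there and at 49.9 CPM (31.6–74.9) in cluster 0. Of *mpx*, 120 of 137 UMIs lay in cluster 4, at 880.2 CPM and in 17.8% of its nuclei, against 54.7 CPM in the Pigmented cluster. *cd74a* stood at 1599 CPM (1394–1826) in cluster 4 and at 1696 CPM (1439–1985) in the Pigmented cluster.

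*ccl25a* and *ccl25b* code for chemokines that draw lymphocytes to epithelium. *ccl25a* led cluster 0 at 3.49-fold (2.78–4.40), and *ccl25b* stood at 1069.5 CPM in cluster 0, 868 CPM in cluster 1 and 1118 CPM in cluster 7, against 440 CPM in cluster 3 and 169 CPM in cluster 4. Mesenchymal nuclei held it too, at 717 CPM (568–894), which overlaps cluster 1 (724–1033).

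Immature TB nuclei read *fgf10a*, which codes for an FGF ligand that mesenchyme sends in many organs. Of its 14 UMIs, 11 lay in Immature TB and 3 in Mesenchymal nuclei, a ratio of 194 (51.1–1080.4) for Immature TB over other nuclei, and 22.2% of the 18 Immature TB nuclei had a UMI against 3.53% of Mesenchymal nuclei.

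Pigment and endothelial transcripts of the Mesenchymal class were counted in some of its 85 nuclei, 5 with a UMI of *pnp4a*, *ltk* or *tfec* and 14 with one of *tie1*, *flt4* or *fli1a*. The 2 nuclei picked for at least 2 UMIs of the pigment genes held 29 of their 32 UMIs, and the 6 picked in the same way for the endothelial genes held 29 of 37, shares that the picking itself raises. *COL6A3*, *col6a2* and *prrx1b* together stood at 567 CPM (154–1451) in the 2 nuclei and at 1136 CPM (605–1943) in the 6, where all 13 UMIs came from 1 nucleus, against 2453 CPM (2160.2–2775) and 2471 CPM (2171–2801) in the rest of the class. The parting was not complete, since the 45 nuclei with at least 2 UMIs of these mesenchyme genes held 11 of the 32 pigment UMIs, in 3 nuclei, and 3 of the 37 endothelial UMIs, in 2 nuclei.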
